A study of Homo sapiens with 12 samples.

How the data were processed

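RNA was sequenced from MIA PaCa-2 cells, an established line derived from a pancreatic ductal adenocarcinoma, exposed to 40 nM SOP1812 or to the control for 6 h or 24 h, in 12 libraries that form 4 groups of 3. Per the labels, the control is named untreated in the sample titles and vehicle (DMSO) in the treatment protocol. Seeding, in units of 1e+06 cells per plate, was 2.5 for 6 h and 1.0 for 24 h, with an overnight wait before exposure, per the labels' protocols, so that exposure time and seeding density changed together. Total RNA was taken with on-column DNase digestion and libraries were made with an mRNA kit from KAPA, per the labels' protocols. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.36, STAR 2.5b and the hg38 genome build were used. The counting tool, the annotation release, the use of strand in counting and the differential expression tool are not given in the sources used here.

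The values analysed were the authors' own comparisons, 1 table per exposure time. Each row gave a gene symbol, the log2 fold change of SOP1812 over control to 3 decimals and a false discovery rate (FDR), an adjusted p-value, both computed by the authors before they deposited the tables. The authors' deposited tables also carried 4 marks, of values 0 and 1, for genes higher or lower and strongly higher or lower. At 6 h the mark for lower genes began at an absolute log2 fold change of 0.45 and the other weaker marks at 0.5, so the marks were not used to call genes, and only the mark for strongly higher genes at 6 h was used, to define a set of large inductions. Values of single libraries were not analysed here. The depth of each library is therefore unknown, no spread between libraries could be computed, and no library could be left out. The labels do not say that the 3 libraries of a group came from separate cultures, so the FDR measures only the spread between those libraries, which may be technical.

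The table for 6 h held 14584 genes and that for 24 h held 14215 rows. In the latter, 20 symbols had been turned into dates, and these rows were kept in counts and left out of every step that needs a name. A gene was called changed at an FDR under 0.05. To compare the times, each FDR was turned back into a p-value (FDR times the highest tied rank, over the number of rows), then into a signed normal z and a standard error (absolute log2 fold change over z). No standard error was taken where the absolute log2 fold change was under 0.02 or p above 0.98, and the other time's was then used. The difference of the log2 fold changes at 24 h and 6 h was put to a two-sided z test with Benjamini-Hochberg adjustment over 14146 genes. This treats the authors' statistic as normal and the libraries of the 2 times as independent. On simulated data for 12796 genes, of which 200 differed between the times, the test recovered 22.4% of differences of 0.5, 62.7% of 1 and 81.8% of 2 on the log2 scale, and 4 of its 115 calls were false. The simulated values were normal and independent, as the test assumes, so they check the back-calculation and not these assumptions. Fewer differences were planted than were called in the data, so the share of false calls may not carry over.

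Gene lists were fixed before the data were examined. Of 36 lists, 33 had at least 5 measured genes and were tested with cameraPR of limma on the signed z, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A correlation estimated from the libraries was not possible with these values, so 0.05 was tried as a second preset. In 400 simulated runs of 14000 independent genes, a list of 30 unchanged genes was called in 1.25% of runs and a list shifted by 1 in 99.8%. Genes of a real list can be correlated, so these shares do not give the rate of false calls here. Overlaps of calls were put to a two-sided Fisher's exact test, and correlations across genes are descriptions, since genes are not independent replicates. For the same reason the p-values of Fisher's test, which takes genes as independent, may be too small.

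Symbols were matched to GENCODE 29 on the GRCh38 assembly, the same build as hg38. Of 14603 symbols, 13543 matched by name, 447 through a synonym and 613 not at all, which left 95.9% of genes at 6 h and 96.0% at 24 h with coordinates. Gene length and transcript GC content of genes that fell or rose were compared with those of genes not called, by a two-sided permutation test of the difference of medians with 100000 permutations, whose smallest possible p is 1e-05, adjusted over 8 tests. The GC content, length and motifs of a transcript were those of the longest transcript of the gene tagged basic in GENCODE 29, which may not be the one expressed. The permutation test called 4.5% of simulated unchanged sets of independent values. Its p-values take genes as independent and may be too small. Odds ratios for the place of genes on chromosomes came from logistic models (statsmodels), which gave 1.01 for a simulated true value of 1 and 2.04 for 2. A search for quadruplex motifs in promoters was designed but not run, because a genome sequence was not used here.

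Genes were named by a rule fixed before the data were examined. It took the 10 highest and the 10 lowest called log2 fold changes at each time. Clone and accession names were left out of these, as were symbols of the LINC, antisense (-AS), microRNA (MIR) and small nucleolar RNA (SNOR) forms. The rule also took up to 3 called members of each list with at least 3 called or with an adjusted list p under 0.05, and a set of 15 genes whatever their value. Of these 15, S100P was not analysed here, and not all of the others are reported. The examples in the text are drawn from the genes this rule gives. LPXN, TXNIP, COL17A1, B3GALT6 and NACC2, which have the smallest FDR, and CTRB1 and RNA28S5 were chosen after their values were seen. Genes with near-identical copies, such as CTRB2 and the ribosomal RNA genes, are uncertain, because reads can be split between copies, and so are genes that overlap others, since the use of strand in counting is not known.

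The alternatives were other thresholds on the FDR and the fold change, centring on the median of all genes, and other statistics and correlations for the lists. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.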

Results

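Gene expression was measured by RNA-seq in MIA PaCa-2 cells, a pancreatic ductal adenocarcinoma line, after exposure to SOP1812. The labels describe this compound as a naphthalene diimide that binds quadruplexes, folded structures that guanine-rich nucleic acids can form. There were 12 libraries, 3 for each of SOP1812 (40 nM) and control at 6 h and at 24 h. The study asked which genes differ between treated and untreated cells at each time. All values below come from the authors' deposited tables of log2 fold changes (SOP1812 over control) and FDR, so the depth of each library is unknown and no spread between libraries is given.

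At 6 h, genes of Wnt signalling were lower in treated cells as a group, a call that depended on the correlation assumed between genes, and the gene for the catalytic subunit of telomerase, TERT, was among those that fell. In the authors' deposited table, TERT had a log2 fold change of -2.29 (FDR 1.78e-07; chromosome 5, 1253147 to 1295069, GENCODE 29 on GRCh38). TERT starts within 5 Mb of the low end of chromosome 5, where 12 of 21 genes fell. The cell cycle inhibitor gene CDKN1A rose, with a log2 fold change of 1.44 in the authors' deposited table (FDR 6.85e-09; chromosome 6, 36676460 to 36687339). Of 14584 genes, 2081 rose and 2133 fell at an FDR under 0.05 in the authors' deposited table. Most changes were small, with a median log2 fold change of 0.46 among genes that rose and -0.52 among genes that fell, and 442 rose and 328 fell by at least 1.

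The Wnt list was the one that passed the list test at 6 h (median log2 fold change -0.17, adjusted p 0.0033 by limma's cameraPR over 33 lists). Of its 55 measured genes, 15 fell, 4 rose and 36 were not called, and the counts were also 15 and 4 when adjusted over the list alone. AXIN1, a scaffold of the complex that degrades beta-catenin, fell by 1.59 on the log2 scale in the authors' deposited table (FDR 2.14e-48; chromosome 16, 287440 to 352673). DVL1, which relays the Wnt signal from its receptor, fell by 1.48 (FDR 3.38e-31; chromosome 1, 1335276 to 1349350) and CCND1, the gene for cyclin D1, by 0.77 (FDR 1.21e-26; chromosome 11, 69641087 to 69654474) in the authors' deposited table. The ligand gene WNT5B had a log2 fold change of -2.26 in the authors' deposited table (FDR 3.86e-06; chromosome 12, 1529891 to 1647243). AXIN1 restrains the pathway, DVL1 acts in its forward direction and CCND1 is among its target genes. AXIN1 and DVL1 start within 5 Mb of chromosome ends where 76 of 157 and 37 of 63 genes fell, while near WNT5B, at another end, 3 of 30 fell. The list call was lost at a preset correlation of 0.05 (adjusted p 0.396), and over the 4 alternatives the adjusted p ranged from 0.003 to 0.396. It was kept by cameraPR with transcript GC content and nearness to a chromosome end fitted out (adjusted p 0.0365).

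The other 32 lists did not pass at 6 h, with adjusted p from 0.0723 to 0.987, and several held called genes in both directions. In the Notch list, 9 of 27 genes fell (10 adjusted over the list alone) and 3 rose, at an adjusted list p of 0.0723. Among them, the ligand genes JAG2 and JAG1 had log2 fold changes of -1.58 and -0.85 and the target gene HES4 -0.78 in the authors' deposited table. Among TGF-beta and BMP genes, 9 of 41 fell and 1 rose, including SKI (-1.19), SMURF1 (-0.71) and ID3 (-1.05) in the authors' deposited table. In the MAPK and RAS list 15 of 53 fell and 5 rose, in axon guidance 15 of 58 fell and 9 rose, in Hippo and YAP 9 of 37 fell and 5 rose, and in Hedgehog 5 of 18 fell and 1 rose. The median log2 fold changes of Hedgehog (-0.26), axon guidance (-0.18) and Notch genes (-0.17) were as low as that of Wnt genes (-0.17) or lower. Those of MAPK and RAS (-0.10), TGF-beta and BMP (-0.08) and Hippo and YAP genes (0.04) were not.

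Cell cycle lists were mixed at 6 h. In some lists that did not pass, the median, mean and test differed in sign, as for S phase and E2F genes (median 0.02, mean -0.05), while in the called lists they had the same sign. Of 39 genes of G2 and mitosis 13 rose and 3 fell, among them KIF20A (0.56) and BUB1 (0.36), which rose, and CDC25B (-0.36), which fell in the authors' deposited table. Of 46 genes of S phase and E2F targets 8 fell and 5 rose. CHAF1A, a chromatin assembly factor gene, fell by 1.53 and the replication licensing gene CDT1 by 0.83, while CCNE1, the gene for cyclin E1, rose with 0.60 in the authors' deposited table. In DNA repair, 7 of 40 fell and 5 rose, and among p53 targets 6 of 29 rose and 4 fell. Replication histone genes had 3 of 44 that rose (1 adjusted over the list alone) and none that fell over all genes. Among apoptosis genes, 9 of 34 rose (12 adjusted over the list alone) and 6 fell. The survival gene MCL1 (0.86) and the death receptor gene TNFRSF10B (0.43) rose and BOK fell by 1.03 in the authors' deposited table.

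Of 31 interferon-stimulated genes 5 rose and 1 fell, including IFIT2 (0.67) and IFIT1 (0.81), which rose in the authors' deposited table. In the unfolded protein and stress list 7 of 26 rose and 3 fell, in cholesterol synthesis 4 of 22 rose and 1 fell, in hypoxia and glycolysis 5 of 27 rose and 3 fell, in immediate early genes 6 of 29 rose and 6 fell, and in NF-kB and inflammatory genes 2 of 17 rose and 3 fell. For lysosome and autophagy 4 of 29 rose, for NRF2 targets 3 of 22 rose, and for mesenchymal genes 3 of 20 rose, among them the protease gene MMP14 (1.67 in the authors' deposited table). Epithelial genes had 1 of 19 that rose and 2 that fell, nucleoside drug handling 1 of 19 and 3, and tubulin and motor genes 2 of 19 and 6. Ribosomal protein genes had 1 of 74 that fell, heat shock 2 of 16, and oxidative phosphorylation 0 called of 32. Counts adjusted over the list alone differed from these by at most 3 genes.

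Lists tied to quadruplexes and telomeres did not pass as groups at 6 h. Of 23 genes for quadruplex helicases and binding proteins 9 fell (10 adjusted over the list alone) and 4 rose, at an adjusted p of 0.309. BLM, a RecQ helicase gene, fell by 0.55 and the topoisomerase gene TOP1 rose with 0.36 in the authors' deposited table. Of 20 genes whose promoters are known for quadruplex motifs 5 fell and 2 rose (adjusted p 0.313), and of 17 telomere genes 3 fell (adjusted p 0.421), among them TERT and the helicase gene RTEL1 (-1.46 in the authors' deposited table).

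Clone and accession names, and LINC, antisense, microRNA and small nucleolar RNA symbols, were left out of the ranks that follow. The highest log2 fold changes in the authors' deposited table belonged to SPON2 (6.80), TRIM72 (6.57), NCCRP1 (6.04), EPPK1 (6.02), ALPP (5.97), PRR35 (5.64), CTRB2 (5.63), LRCOL1 (5.51), SEMA4G (5.37) and FUT3 (5.32). The standard error calculated back from the FDR was above 1 for 9 of these 10. The lowest in the authors' deposited table were ROR2 (-4.35), ST3GAL1 (-4.25), ZNF469 (-3.95), RNA18S5 (-3.50), RAB40C (-2.90), RNA45S5 (-2.84), CRIPAK (-2.72), FAM20C (-2.68), KIAA1656 (-2.65) and ZFPM1 (-2.53), with a standard error above 1 for 2 of 10. The calls of ROR2 and ST3GAL1 were lost at an FDR under 0.01. By FDR, the leading genes of the authors' deposited table were B3GALT6 (-2.23, FDR 1.69e-60) and NACC2 (-1.97, FDR 2.69e-59), both chosen after their values were seen.

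At 24 h, genes of DNA replication, ribosomes and cholesterol synthesis were lower in treated cells. FEN1, a flap endonuclease gene of lagging strand synthesis, fell by 1.05 (FDR 2.24e-26; chromosome 11, 61792637 to 61797244) and PCNA, the gene for the sliding clamp, by 1.18 (FDR 5.05e-23; chromosome 20, 5114953 to 5126626) on the log2 scale in the authors' deposited table. INSIG1, a sterol sensor gene, fell by 1.69 (FDR 2.61e-55), a 3.22-fold lower level in the authors' deposited table (chromosome 7, 155297776 to 155310235). ATF3, a stress-responsive transcription factor gene, rose with a log2 fold change of 2.13 in the authors' deposited table (FDR 6.59e-29; chromosome 1, 212565334 to 212620777). Of 14215 rows, 2001 rose and 2158 fell in the authors' deposited table, with median log2 fold changes of 0.48 and -0.41, and 383 rose and 198 fell by at least 1.

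Of the 33 lists, 12 passed at 24 h, 10 lower and 2 higher. Some genes are on more than 1 list, as ATF3 is on those of unfolded protein and stress and of immediate early genes. The 12 calls are therefore not all separate results. In the S phase and E2F list, 38 of 46 genes fell, 1 rose and 7 were not called, and the counts were also 38 and 1 when adjusted over the list alone (median log2 fold change -0.56, adjusted p 4.58e-28). Besides FEN1 and PCNA, the polymerase gene POLA2 fell by 0.68 in the authors' deposited table. In G2 and mitosis 16 of 39 fell (19 adjusted over the list alone) and none rose over all genes (adjusted p 3.62e-07), with CDC25B, CCNA2 and ANLN at -0.44, -0.58 and -0.48 in the authors' deposited table. In DNA repair 15 of 40 fell and 2 rose (adjusted p 0.0031), including the exonuclease gene EXO1 (-0.68) in the authors' deposited table.

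Ribosomal protein genes moved together by a small amount, with 57 of 74 lower (68 adjusted over the list alone) and none called higher, a median of -0.30 and an adjusted p of 2.46e-13. RPL3 fell by 0.68, RPL36 by 0.51 and RPL10A by 0.47 in the authors' deposited table. Of 22 genes of cholesterol synthesis 15 fell and none rose over all genes (16 and 1 adjusted over the list alone; adjusted p 7.95e-09), among them SREBF2, the transcription factor gene of the pathway (-0.68), and MSMO1 (-0.91) in the authors' deposited table. In oxidative phosphorylation 13 of 32 fell (adjusted p 5.23e-04), with SDHA at -0.35 and CYC1 at -0.41, and in heat shock 11 of 16 fell (adjusted p 0.0011), with HSPE1 at -0.45, DNAJA1 at -0.46 and HSPA8 at -0.61 in the authors' deposited table. Both of these counts were unchanged when adjusted over the list alone.

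The remaining calls at 24 h held fewer or mixed members. Of 26 unfolded protein and stress genes 13 fell and 5 rose (14 and 6 adjusted over the list alone; adjusted p 0.0077), where ATF3 rose while PSAT1 (-0.84), of serine synthesis, and DDIT4 (-1.22) fell in the authors' deposited table. Of 23 quadruplex helicase and binding protein genes 12 fell (13 adjusted over the list alone) and 1 rose (adjusted p 0.0041), including HNRNPA1 (-0.59), DNA2 (-0.46) and CNBP (-0.41) in the authors' deposited table. Of 27 Notch genes 11 fell and 3 rose (adjusted p 0.0101), with HES4 at -1.36, NOTCH3 at -1.27 and JAG1 at -0.65 in the authors' deposited table. The 2 higher lists were NF-kB and inflammatory genes, with 5 of 16 higher (6 adjusted over the list alone; adjusted p 0.0101), and immediate early genes, with 8 of 28 higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p 0.0306). TNFAIP3 (2.12), LIF (1.18) and RELB (0.87) rose in the former, while in the latter the ETS factor gene ETV4 rose with 0.64 and JUND fell by 0.67 in the authors' deposited table.

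At a preset correlation of 0.05 the calls of DNA repair (adjusted p 0.0706), NF-kB (0.0706), unfolded protein and stress (0.0717), quadruplex helicases and binding proteins (0.0568), Notch (0.09) and immediate early genes (0.170) were lost, and with the log2 fold change as the statistic the same 6 and oxidative phosphorylation (0.127) were lost. Notch genes lost their call in all 4 alternatives (adjusted p from 0.0641 to 0.116) and immediate early genes in 3 of 4 (from 0.0384 to 0.170). Over the 4 alternatives, the highest adjusted p of the 5 lists that kept their call in all of them was 0.0257, that of G2 and mitosis.

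The other 21 lists did not pass at 24 h (adjusted p from 0.122 to 0.937). In the p53 list, 8 of 29 genes rose and 4 fell, where GADD45A rose with 1.27 and BAX fell by 0.44 in the authors' deposited table. In TGF-beta and BMP 11 of 41 rose and 6 fell, with the matrix gene LTBP2 at 2.08, the BMP antagonist gene NOG at 1.23 and the BMP target gene ID1 at -0.999 in the authors' deposited table. Of 54 Wnt genes 13 fell and 6 rose, of 57 axon guidance genes 16 fell and 9 rose, of 53 MAPK and RAS genes 10 fell and 6 rose, of 37 Hippo and YAP genes 8 fell and 9 rose, and of 17 Hedgehog genes 6 fell and 3 rose. For 19 genes of nucleoside drug handling 4 fell and 2 rose, with RRM2 (-0.88) and TYMS (-0.59), of deoxynucleotide synthesis, among those that fell in the authors' deposited table. Counts of genes that rose and fell were 4 and 2 of 29 interferon-stimulated genes, 5 and 1 of 43 replication histones, 4 and 8 of 27 hypoxia and glycolysis genes, 6 and 8 of 22 NRF2 targets, and 3 and 8 of 19 tubulin and motor genes. They were 6 and 6 of 34 apoptosis genes, 3 and 3 of 20 mesenchymal genes, 1 and 2 of 19 epithelial genes, 3 and 5 of 29 lysosome genes, 4 and 4 of 17 telomere genes, and 1 and 3 of 20 genes with known promoter quadruplexes. Adjusted over the list alone, counts other than that of ribosomal proteins differed by at most 3 genes.

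With the same names left out, the highest log2 fold changes at 24 h in the authors' deposited table were those of EPPK1 (6.71), PDE6G (5.69), SPON2 (5.60), CTRB2 (4.998), PRR35 (4.78), AP1M2 (4.72), GZMM (4.35), TCN2 (4.17), SRMS (3.77) and C9orf173 (3.75), with a standard error above 1 for 8 of the 10. The lowest in the authors' deposited table were RNA18S5 (-3.70), IL37 (-3.65), ZNF423 (-3.19), RTL1 (-3.18), REEP1 (-2.96), TERC (-2.90), VTRNA2-1 (-2.80), ENHO (-2.67), RNA45S5 (-2.64) and HEY1 (-2.47), with a standard error above 1 for 4 of the 10. The calls of SRMS and C9orf173 among the highest and of IL37, ZNF423, RTL1, REEP1 and HEY1 among the lowest were lost at an FDR under 0.01. TERC is the RNA template of telomerase, and its FDR of 2.66e-10 in the authors' deposited table was the second smallest of these 10, after that of RNA45S5 (5.81e-19). Chosen after their values were seen, LPXN (1.87, FDR 7.03e-107), TXNIP (2.28, FDR 1.19e-77) and COL17A1 (1.42, FDR 2.98e-69) had the smallest FDR in the authors' deposited table.

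Markers of cell types that a culture of this line should not hold were counted as well. Of 16 listed immune cell markers 5 were measured, of which 1 rose at 6 h and 2 at 24 h, and of 12 listed fibroblast markers 7 were measured, of which 1 rose at 6 h while 1 rose and 1 fell at 24 h. Of the endothelial markers 3 were measured and 1 rose at 24 h. The single measured gene of the acinar and islet list, CTRB1, rose at 6 h (4.68, standard error 1.39) and was not called at 24 h (2.15, FDR 0.316) in the authors' deposited tables. CTRB2, a near-identical copy that is not on the list, was called higher at both times. No mitochondrially encoded gene was analysed here.

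Several genes were followed whatever their value. In the authors' deposited tables for 6 h and 24 h, MYC had log2 fold changes of -0.02 (FDR 0.943) and -0.07 (FDR 0.795), and VEGFA had -0.04 (FDR 0.841) and 0.002 (FDR 0.993). BCL2 fell at 6 h (-0.58, FDR 0.0399) and was at -0.48 at 24 h (FDR 0.111), and PARD6A fell at 6 h (-0.52, FDR 0.033) and was at -0.23 at 24 h (FDR 0.412) in the authors' deposited tables. TERT (-1.03, FDR 0.0227), TP73 (-0.61, FDR 0.0387) and DVL1 (-0.77, FDR 6.03e-09) were lower at 24 h as well, after -1.88 for TP73 at 6 h (FDR 1.57e-12), in the authors' deposited tables. MAPK11, a p38 kinase gene, fell at both times (-0.71, FDR 5.90e-05, and -1.72, FDR 6.71e-22), and CDKN1A was still higher at 24 h (1.28, FDR 6.01e-06) in the authors' deposited tables. WNT5B was at -0.57 at 24 h (FDR 0.207), GLI1 at -0.66 and -1.84 (FDR 0.459 and 0.0401), HMOX1 at -0.43 and -0.48 (FDR 0.0666 and 0.0382) and MDM2 at 0.04 and 0.27 (FDR 0.841 and 0.0322) in the authors' deposited tables. The call of MDM2 at 24 h was lost when fold changes were centred on the median of all genes.

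The responses at the 2 times shared genes, and many genes also differed between them. Over 14195 genes in both tables, 633 rose at both times where independent lists would give 292.6 (odds ratio 3.45, two-sided Fisher's exact p 9.26e-100), and 640 fell at both times where 324.0 would be given (odds ratio 2.98, p 2.17e-81). Opposite calls were rarer than for independent lists, with 107 genes that rose and then fell against 315.3 and 123 that fell and then rose against 300.7. Among the latter were EGFR (-0.41 and 0.40) and the kinase gene PLK3 (-0.73 and 0.66), and among the former ANLN (0.30 and -0.48) and CCNE1 (0.60 and -0.35) in the authors' deposited tables. Across all genes, which are not independent replicates, Spearman's rho was 0.324 and Pearson's r 0.404. The controls were separate libraries at each time.

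**Figure D1:**
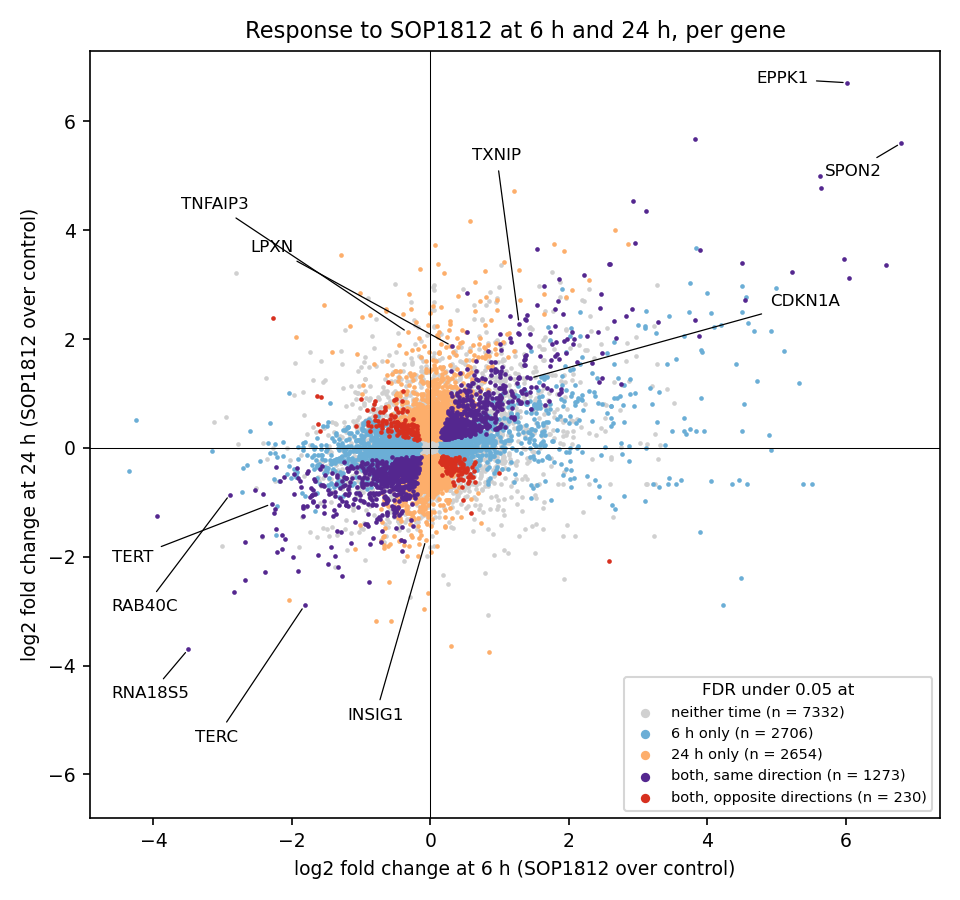
Each point is 1 of 14195 genes, with its log2 fold change at 6 h (horizontal) and at 24 h (vertical), SOP1812 over control, from the authors' deposited tables, and colours give the times at which its FDR was under 0.05. The 1273 genes called in the same direction at both times lie at the lower left and upper right, and 230 genes were called in opposite directions.

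The difference between the times was tested directly. Of 14146 genes, 3155 differed at an adjusted p under 0.05 by the z test, 1625 more positive and 1530 more negative at 24 h. Of 2706 genes called at 6 h alone, 1219 differed between the times, and of 2654 called at 24 h alone, 1286 did, so a call at 1 time was often not a shown difference. Of the 33 lists, 11 differed, 9 lower and 2 higher at 24 h than at 6 h. The largest shift downward in median was that of S phase and E2F genes (-0.48, adjusted p 2.24e-17), and the largest upward was that of NF-kB genes (0.60, adjusted p 0.0166). The Wnt list, called at 6 h alone, did not differ between the times (median difference 0.20, adjusted p 0.112), nor did the list of quadruplex helicases and binding proteins (-0.02, adjusted p 0.167), called at 24 h alone. A preset correlation of 0.05 left 7 of the 11 and the log2 fold change as the statistic left 4. NF-kB genes were among those lost in both (adjusted p from 0.0313 to 0.0841 over 3 alternatives), and TGF-beta and BMP genes, the other list that was higher, were lost in all 3 (0.0743 to 0.240).

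**Figure D2:**
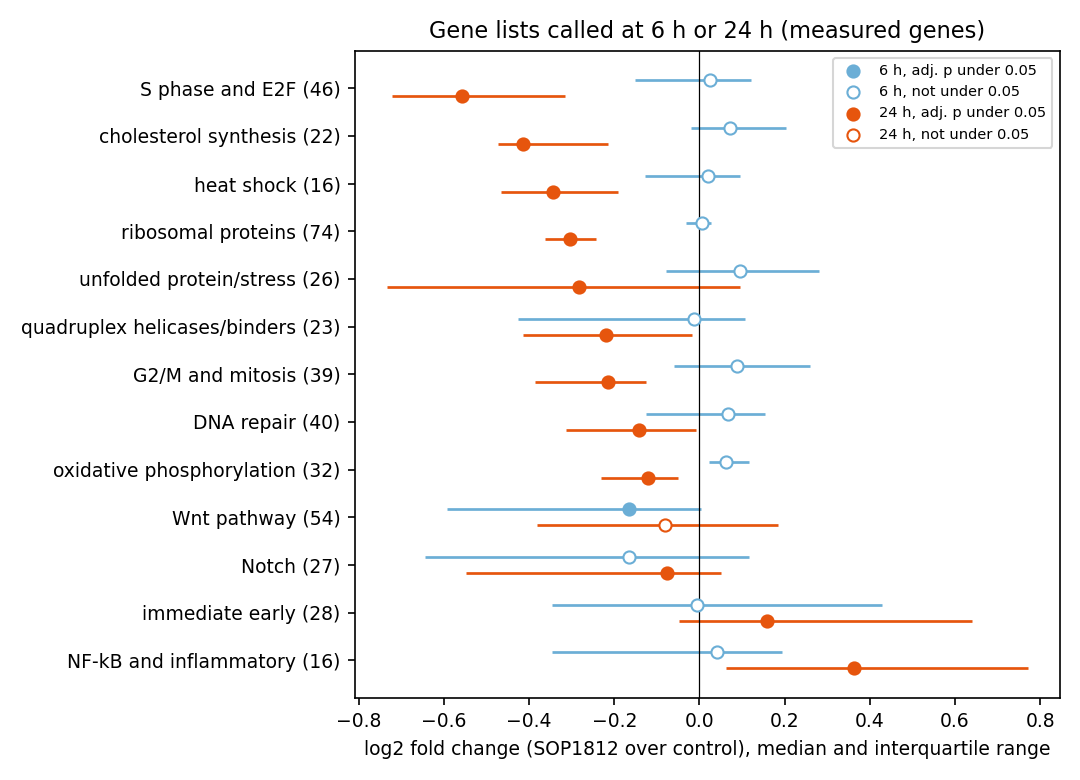
Points are the median log2 fold change (SOP1812 over control) of each gene list called at 6 h or 24 h, and bars its interquartile range, with the number of genes measured at 24 h in brackets, filled where the adjusted list p was under 0.05. The list of S phase and E2F genes has medians of 0.02 at 6 h and -0.56 at 24 h, and that of Wnt genes is filled at 6 h only.

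Genes that fell had GC-rich transcripts. GC content and gene length can also carry technical bias between treated and control libraries, which could not be checked without values of single libraries. At 6 h, the median transcript GC content was 56.6% among 2089 genes that fell, 44.8% among 1979 that rose and 49.1% among 9922 not called, so the former lay 7.50 percentage points higher and the latter fell below by -4.31 (adjusted p 2e-05 for each, from the smallest p the permutations can give). The share of genes that fell at 6 h went from 6.79% in the lowest of 10 equal groups by GC content to 32.1% in the highest, and the share that rose from 22.7% to 6.58%. At 24 h the genes that fell were again higher in GC content (52.9% against 48.9%, a difference of 4.02, adjusted p 2e-05), and those that rose were not distinguished (-0.44, adjusted p 0.315). Gene length differed less regularly. Genes that rose were longer at 6 h (35.1 against 28.0 kb, adjusted p 2e-05) and at 24 h (by 5.29 kb, adjusted p 0.000128), and genes that fell at 24 h were shorter (-4.29 kb, adjusted p 0.000213), while those that fell at 6 h were not distinguished (-0.946 kb, adjusted p 0.365). Among called genes with an absolute log2 fold change of at least 0.58, the direction of length turned for genes that rose (-6.83 kb at 6 h and -4.48 kb at 24 h), those that fell were shorter at 6 h (-4.26 kb) and not distinguished at 24 h (-3.27 kb, adjusted p 0.134). Under that setting, the GC content of genes that rose was not distinguished at 6 h (-0.55, adjusted p 0.4) and lay 2.84 points higher at 24 h (adjusted p 2.67e-05).

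**Figure D3:**
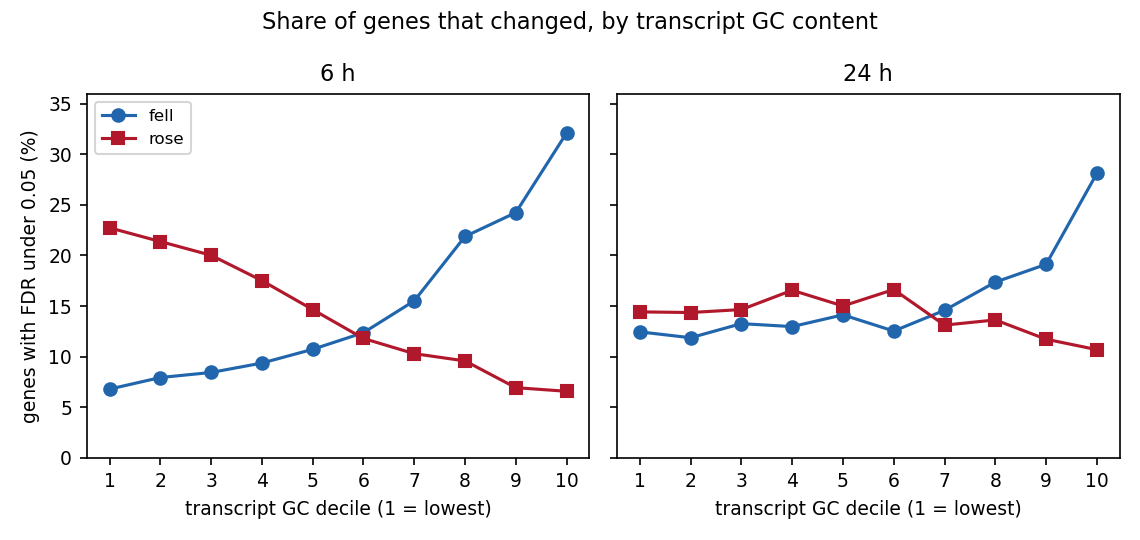
Share of genes that fell or rose (percent, FDR under 0.05 in the authors' deposited tables) in each of 10 equal groups of genes ordered by transcript GC content, at 6 h and 24 h. The share that fell rises to 32.1% at 6 h and 28.1% at 24 h in the group with the highest GC content.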

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

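The test of a common scaling was chosen only after its result was seen, and the other test of the ribosomal protein genes before. The results listed here are those in which the responses at 6 h and 24 h differed by the z test computed from the authors' deposited tables, at an adjusted p under 0.05. There were 3155 such genes of 14146 tested. Seeding density differed between the times along with exposure, so a difference between times is also one between densities.

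Of the gene lists, 9 were lower at 24 h than at 6 h, by medians on the log2 scale of -0.48 for S phase and E2F, -0.40 for cholesterol synthesis, -0.39 for G2 and mitosis, -0.35 for heat shock, -0.31 for unfolded protein and stress, -0.30 for ribosomal proteins, -0.20 for oxidative phosphorylation, -0.17 for lysosome and autophagy and -0.16 for DNA repair. The other 2 were higher, TGF-beta and BMP by 0.16 and NF-kB and inflammatory genes by 0.60. At a preset correlation of 0.05 both of these, lysosome and autophagy and DNA repair lost their calls. With the log2 fold change as the statistic these 4 and oxidative phosphorylation, unfolded protein and stress and heat shock did, and by ranks TGF-beta and BMP did.

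Of 115 genes named in the text, 64 differed, 32 lower and 32 higher at 24 h, with adjusted p from 8.60e-37 (LPXN) to 0.0424 (ST3GAL1). Many of the 115 were named for an extreme log2 fold change or a small FDR at 1 time, values that also enter the difference. Their share that differed may therefore be too high and cannot be set against that of all genes. Among cell cycle, replication and repair genes the difference in log2 fold change from the authors' deposited tables was -1.19 for FEN1, -1.06 for PCNA, -0.95 for CCNE1, -0.90 for RRM2, -0.83 for EXO1, -0.78 for ANLN, -0.59 for KIF20A, -0.55 for POLA2, -0.55 for TYMS, -0.46 for BUB1 and -0.39 for CCNA2, and 0.56 for CHAF1A and 0.81 for CCND1. In metabolism, ribosome and folding genes it was -1.62 for INSIG1, -0.95 for MSMO1, -0.90 for PSAT1, -0.76 for SREBF2, -0.59 for RPL3, -0.46 for RPL36, -0.46 for HSPE1, -0.46 for SDHA, -0.39 for HNRNPA1 and -0.34 for CYC1 (authors' deposited tables).

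For signalling, stress and death genes, the differences from the authors' deposited tables were -1.24 for NOTCH3, -1.18 for MMP14, -1.01 for MAPK11, -0.71 for IFIT1, -0.65 for IFIT2, -0.64 for MCL1, -0.58 for HES4 and -0.40 for TNFRSF10B. Upward differences in the authors' deposited tables were 0.49 for BOK, 0.53 for ETV4, 0.71 for DVL1, 0.81 for EGFR, 0.91 for JAG2, 0.95 for RELB, 1.01 for SMURF1, 1.06 for LIF, 1.07 for SKI, 1.17 for GADD45A, 1.197 for AXIN1, 1.26 for TP73, 1.36 for NOG, 1.39 for PLK3, 1.59 for ATF3, 1.68 for WNT5B, 1.98 for LTBP2 and 2.45 for TNFAIP3. Among the genes with extreme values or the smallest FDR in the authors' deposited tables it was -6.16 for LRCOL1, -6.03 for SEMA4G and -2.63 for ENHO, and 0.94 for FAM20C, 1.00 for TXNIP, 1.12 for COL17A1, 1.12 for NACC2, 1.56 for LPXN, 1.76 for ZFPM1, 1.89 for B3GALT6, 1.91 for CRIPAK, 2.04 for RAB40C, 2.34 for KIAA1656, 2.69 for ZNF469 and 4.75 for ST3GAL1. The standard error of the difference was 2.35 for LRCOL1, 2.10 for SEMA4G and 1.82 for ST3GAL1. A gene chosen as extreme at 1 time can lie nearer to no change at the other through that choice alone.

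Of 74 ribosomal protein genes, 72 had log2 fold changes below 0 at 24 h in the authors' deposited table, with a median of -0.30. The ribosomal median lay apart from that of all genes by -0.33, more than the interquartile range of 0.12. This gap is no separate evidence against a scaling of all genes, since the list had already been called for differing from other genes. For short transcripts, a smooth fit on transcript length and GC content was taken out, and the median was then -0.41, lower than the -0.30 before it. The length was that of the longest annotated transcript, with a median of 1170.5 bases for these genes. This argues against that length as the whole cause. The length of the transcripts expressed was not measured, so a bias by that length stays open. Reads shared with the many pseudogenes of this family, library depth and seeding density stay open as untested, and so does an effect of the longer exposure.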

How the results depend on the processing

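Restricting length and GC content to protein-coding genes and fitting GC content and chromosome ends out of the list statistic were chosen after the data were seen. No paired analysis was possible because the authors' deposited tables carry no values of single libraries. For the same reason leaving out replicates, other splits of the libraries, normalizations, count tests, pseudocounts, expression filters, expression-matched genes, adjustment from raw p-values and an estimated correlation were not run, nor were the promoter motif variants, which need a genome sequence not used here. Depth is unknown, so what low counts limit could not be assessed beyond the back-calculated standard errors.

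Counts of genes that rose and fell moved most with a fold threshold, by construction: 794 and 909 at 6 h and 800 and 606 at 24 h at an absolute log2 fold change of at least 0.58, and 442 and 328, then 383 and 198, at 1. At an FDR under 0.01 the count that rose at 24 h was 1297, and the other 3 counts (1413, 1544 and 1547) were within 1.5 times, as were those at 0.1 and after centring. Centring took the share of calls that rose from 49.4% to 45.0% at 6 h and from 48.1% to 42.7% at 24 h. Of the named genes called, centring lost 0 of 72 at 6 h (9 at an FDR under 0.01) and 2 of 90 at 24 h (MDM2 and NCCRP1; 18 at 0.01), and turned none. Genes that differed between the times numbered 4095 at 0.1 and 3164 after centring. The overlap odds ratios rose to 4.16 and 3.46 at an FDR under 0.01 and to 8.41 and 6.46 with the 0.58 threshold. Spearman's rho was 0.430 over genes called at 1 or both times.

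Lists called were 0 at 6 h by cameraPR with a preset correlation of 0.05 (2 at an unadjusted p under 0.05), 1 with the log2 fold change, 1 by ranks and 2 with GC content and chromosome ends fitted out, which added lysosome and autophagy. At 24 h they were 6, 5, 10 and 11, all among the 12, and for the difference 7, 4 and 11 in the first 3 settings, where ranks kept 10 of the original 11, lost TGF-beta and BMP and added NRF2 targets. Ranks at 24 h lost Notch and immediate early genes, and fitting GC content and chromosome ends out lost Notch. With the 0.58 threshold, the length difference of genes that rose was -6.83 kb at 6 h and -4.48 kb at 24 h, turned from positive, and that of genes that fell -4.26 kb at 6 h, now past the threshold, and -3.27 kb at 24 h, no longer so. The GC difference of genes that rose was -0.55 at 6 h, no longer past the threshold, and 2.84 at 24 h, turned from negative. The cause of these changes was not tested. In protein-coding genes alone, the length difference of genes that fell went from -0.946 to -2.16 kb at 6 h, still not past the threshold, and from -4.29 to -7.05 kb at 24 h, and the other 6 length and GC differences kept their direction and side of the threshold.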

Other observations

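Chosen after the data were seen were the counts by gene class, the test of chance and both comparisons with uncalled imprecise genes for the large inductions, the other distances for chromosome ends and the search of transcripts for motifs. The pattern at chromosome ends was noticed before its tests were written. The distance and the set of genes left out with a few ends were redefined after a first result, which moved the odds ratios little.

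Counts by class of RNA, with no test of a difference between classes, were as follows. At 6 h, 36 of 172 small nucleolar RNA genes, which guide the modification of ribosomal RNA, fell and none rose, and 90.7% had log2 fold changes below 0 (median -0.80), while at 24 h 1 of 163 rose and none fell (median -0.11). Of long non-coding RNA genes, 142 of 737 rose and 45 fell at 6 h (median 0.28) and 136 of 706 rose and 20 fell at 24 h (median 0.35). Of 12628 protein-coding genes 1799 rose and 1984 fell at 6 h, and of 12385 at 24 h 1747 rose and 2107 fell. TERC fell at both times in the authors' deposited tables (-1.82, FDR 0.000137, and -2.90, FDR 2.66e-10; chromosome 3, 169764520 to 169765060), as did RNA45S5, the ribosomal RNA precursor (-2.84 and -2.64), while RNA28S5 was not called at either time (0.001, FDR 0.999, and -0.69, FDR 0.124). Small nucleolar RNAs, TERC and ribosomal RNAs mostly lack the poly(A) tail by which mRNA kits select, and most small nucleolar RNA genes lie inside introns of other genes, so a difference in carry-over between the libraries was not tested and stays open for them.

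Genes near chromosome ends fell more often at 6 h than others did, although 1405 of the 2089 genes that fell lay elsewhere. Of the genes named above, TERT, AXIN1, DVL1, JAG2 and RTEL1 start within 5 Mb of an end. So do, among others, B3GALT6, NACC2, RAB40C, FAM20C, HES4, SKI, CHAF1A, CDT1, BOK and MAPK11. The falls of all such genes at 6 h cannot be told apart from this pattern. CCND1 and JAG1 start elsewhere. Of 1880 genes that start within 5 Mb of an end 36.4% fell, against 11.6% of 12110 others (odds ratio 4.36, 95% interval 3.91 to 4.86), and the odds ratio was 4.98 for 3 Mb, 3.10 for 10 Mb and 2.44 at 24 h. Argued against as the whole cause were transcript GC content (odds ratio 3.06 with it as a term, 2.72 to 3.44), the mean transcript GC content of genes within 500 kb (2.62, 2.30 to 2.98), short genes (4.48, 4.01 to 5.01) and a few chromosome ends (4.03, 3.57 to 4.56). For the last, the 3 ends with most such genes were left out, with every gene nearer to that end than to the other. With these GC contents and lengths together the odds ratio was 2.55 (2.23 to 2.91). The intervals are too narrow, since neighbouring genes are not independent, and the GC content of the region's genomic sequence, which was not measured here, stays open, as does a bias between the libraries that these terms miss. A response of chromosome-end genes to the compound may be a further explanation, as a hypothesis.

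Some large inductions had imprecise fold changes. Of 65 genes that the authors' deposited table marks as strongly higher at 6 h with a standard error above 1, 60 were also in the table for 24 h, and 75% of these (45; 95% interval 62.1 to 85.3) were above 0 there, of which 9 were called. The share was 52.9% among all genes but 67.0% among 318 uncalled genes with as large a standard error, within that interval, so chance from low counts stays open for the group. Read-through from an upstream gene stays open, as 29.3% of 58 had a measured gene ending within 10 kb upstream on the same strand against 19.3% of other genes (odds ratio 1.74, 0.986 to 3.06). Against the 598 such uncalled genes with coordinates at 6 h, the read-through odds ratio was 2.34 (1.27 to 4.30).

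A hypothesis was that quadruplex motifs in the mature transcript mark the genes that fell at 6 h. A motif on the sense strand was present in 40.2% of their transcripts and 25.5% of others (odds ratio 1.97), and one on the opposite strand, which the RNA does not hold, in 49.1% and 30.8% (odds ratio 2.16). With GC content and transcript length as terms the odds ratio was 1.10 (0.984 to 1.22) for the sense strand and 1.05 (0.939 to 1.18) for the opposite one, so a motif effect may be small or missing and cannot be told apart from GC content here.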
